A study of Bos taurus with 8 samples.

How the data were processed

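Values of 8 arrays of 2 colours from a bovine macrophage cell line were used, 4 with FhWey-ES and 4 with FhWild-ES. Each array holds ES-exposed cells in Cy5 and control cells in Cy3, per the labels. The deposited scanner files give the intensity of each spot in both channels with its local background, as the authors' scanner software wrote it. The deposited series matrix holds the log10 ratio of Cy5 over Cy3 that the authors took from the scanner software. It matched the log10 ratio in the scanner files with a largest difference of 0, and 0 of its columns belonged to no sample. Agilent Feature Extraction is given as version 10.7.3.1 per the submitters' processing notes and as version 10.10.1.1 per the file headers, and which one made the values was not settled. The array design is 023647 and its probes are placed on UMD_3.1, per the file headers.

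Log2 ratios were recomputed from the spot intensities in R 4.3.3 with limma 3.58.1. Mean signals were corrected for the local median background with normexp and an offset of 50, and each array was normalized by loess with its 1417 control spots at weight 0. Spots that the scanner software had marked as outliers, 157 over all arrays, were set aside before the background correction. A mark on the local background was also taken as an outlier mark, which was settled after the data were examined. The reason was 1 spot of FhWild-ES replicate 3 with a local background of 117995, which moved the Cy3 mean fitted by normexp from 4.63 to -695. On FhWey-ES replicate 2 a background of 1343 moved it from -3.62 to -45.2. Spots of the same probe were averaged.

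Of 43653 probes, 30293 were kept because they were well above background on at least 3 of 4 arrays in at least 1 of the 4 sets of isolate and channel. Each gene was represented by the probe with the highest mean intensity over the 8 arrays, which left 17647 features, 12700 with a gene symbol and 4947 without. Probes were named from the supplied RefSeq gene table and the file annotation, and 35198 probes carried 1 of 17373 gene symbols. The systematic name matched the RefSeq table for 26743 probes and another accession of the probe for 1816. For 5113 probes the name in the files was a current symbol, for 148 an older symbol and for 1378 it was kept as given. No symbol was found for 8452 probes, and 3 matched several genes.

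Median signal over the non-control spots was 100.6 to 129.7 in Cy3 and 105.6 to 161 in Cy5. The SD of the log2 ratio over genes was 0.118 to 0.138 on FhWey-ES arrays and 0.175 to 0.224 on FhWild-ES arrays. Correlations of log2 ratios between arrays were 0.271 to 0.663 within FhWey-ES and 0.0475 to 0.837 within FhWild-ES, and Cy3 intensities correlated at 0.998 to 0.999.

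The 8 arrays were fitted together with a mean for each isolate (lmFit and eBayes, 6 residual and 7.09 prior degrees of freedom). Tests were made of FhWey-ES against control, FhWild-ES against control and FhWild-ES minus FhWey-ES, each two-sided with Benjamini-Hochberg adjustment over features and a threshold of 0.05. Rose and fell refer to an adjusted p under that threshold, and other probes of a gene were read at an unadjusted p under 0.05. The control channel was compared between the sets of arrays with limma after quantile normalization of the average intensities. In Cy3, arrays of the same replicate number deviated together, with correlations of 0.39, 0.30, 0.19 and 0.53 for the 4 numbers, so the block is given beside that comparison; this pairing comes from the data, not from the labels. No array had the dyes exchanged, so a probe-specific dye effect stays in each ratio to control and cancels in the difference of the isolates if it is constant.

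Gene lists numbering 29, 22 of pathways and 7 of cell types, were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, for lists with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it, and 34 features with a missing value were left out of list tests. The samples' groups, the tests, the lists and the alternatives were fixed before the data were examined, except where the text says otherwise. Genes were named by a rule: those with a symbol, adjusted p under 0.05, the same sign on every array (for the difference, no overlap of the 4 and 4 ratios) and signal well above background in at least 1 channel on every array. From these the 8 largest rises and 8 largest falls of each comparison were taken, with the largest called rise and fall of each pathway list. A further 10 immune genes were named whatever their result, and a gene that the rule took is not reported here, though counts include it. RPS27A in FhWey-ES and PDIA6, CALR, CTSB, LAMP1, COL6A1, SYVN1, SPI1, CD247, CD3D, MUC1, SRSF5, SRSF4, MAT2A and OGT were chosen as examples after their values were seen, as were ADM, NDRG1 and ANKRD37.

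On simulated data with 200 changed genes of the observed spread, limma recovered 79.1% of 1.2-fold changes in FhWey-ES, 86.6% in FhWild-ES and 26.9% in the difference, and 100% of 1.5-fold and 2-fold changes in each. Unchanged genes called were 10, 15 and 16. The simulated arrays were independent and had the same spread per gene for both isolates, while the measured spread differed between them. These rates may therefore not hold for the measured arrays. The alternatives covered background correction, normalization within and between arrays, the filter, outlier spots, the choice of probe, the deposited ratios, the estimate of the spread, a fold threshold, the replicate number as a block and each array left out. Alternatives added after seeing the data were agreement of another probe, arrays 2 and 3 alone, the mean of the hypoxia list as a covariate, and removal of a trend with probe GC content. Spike-in and other control spots were left out of all gene tests.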

Results

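Gene expression was measured in BOMA cells, a bovine macrophage cell line, that had been exposed to excretory-secretory products (ES), the mixture of molecules the liver fluke Fasciola hepatica releases into its host. ES came from 2 fluke isolates, FhWey and FhWild, and the series sets a wild isolate against a laboratory one. Each of 8 arrays of 2 colours carried RNA of ES-exposed cells in Cy5 and RNA of control cells in Cy3, with 4 arrays per isolate. The labels give ES at 10 µg/ml, lipopolysaccharide (LPS, a bacterial product that activates macrophages) at 8.9 µg/ml, and an exposure of 26 h for FhWey-ES and 24 h for FhWild-ES. They leave open whether the control cells also received LPS, so a ratio in these data is ES-exposed over control and a part owed to LPS was not separable from it. The labels speak of 4 stimulated and 4 control wells and also of technical replicates. The spread between arrays, and every p-value computed from it, may therefore hold only technical spread. Of 43803 non-control spots per array, 64 to 67.4% in Cy3 and 65.2 to 71.5% in Cy5 were well above background, and 0 spots were saturated. After the filter on dim probes, 17647 features remained, 12700 of them with a gene symbol, and the number of arrays limits the precision of each value. Counts of genes below are counts of features, and a probe without a symbol counts as a gene of its own.

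The comparison of FhWey-ES with control cells asked which macrophage genes the products of this isolate alter. ENO1, the glycolytic enzyme enolase, rose by a log2 ratio of 0.49 ± 0.13 (SD, n = 4 arrays; adjusted p = 0.000292), and 2 of its 4 other probes moved the same way at an unadjusted p under 0.05. DNAJB9, a co-chaperone of the endoplasmic reticulum, rose by 0.40 ± 0.07 (adjusted p = 0.000631). NFKBIA, the inhibitor that holds NF-kB in the cytosol, rose by 0.39 ± 0.07 (adjusted p = 0.00686). Its 3 other probes had a median of 0.03, and 1 of them moved the same way. GPRC5B, an orphan membrane receptor, fell by 0.33 ± 0.06 (adjusted p = 0.00138), and ZNF341, a zinc finger activator of the STAT3 gene, fell by 0.39 ± 0.07 (adjusted p = 0.000978). In all, 568 genes were higher and 395 lower in limma, with a median absolute log2 ratio of 0.216, a 1.16-fold change. Of these, 403 of the higher and 291 of the lower carried a gene symbol. The split of the whole count depended on normalization, and median centring gave 10638 higher and 2252 lower. A change of at least 1.5-fold was reached by 6 genes in the main setting, all higher. The offset of the background correction, added to both channels, draws the ratio of a dim spot toward 0 by definition. Fold sizes and fold counts, here and in the other comparisons, may therefore understate changes of RNA, and by how much was not tested. Over the alternatives the log2 ratio ran from 0.299 to 1.11 for ENO1, from -0.914 to -0.354 for ZNF341 and from -1.47 to -0.224 for FBXO48.

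Most of the largest rises in FhWey-ES were not seen in other probes of the same gene, where the gene had any. The probe of SS18L1, a subunit of a neuronal chromatin remodelling complex (UMD_3.1 chromosome 13, 55538897 to 55538956), rose by 0.64 ± 0.04, while its 2 other probes had a median of 0.03. The probe of PTPRC, the leukocyte phosphatase CD45 (chromosome 16, 79592585 to 79592644), rose by 0.63 ± 0.08, and its other probe read 0.08. ATOSB rose by 0.65 ± 0.04 with another probe at 0.03, TYK2, a Janus kinase of interferon and interleukin receptors, by 0.59 ± 0.07 with another probe at -0.02, and SPIN1, a histone reader, by 0.58 ± 0.05 with others at a median of -0.02. SV2A, a synaptic vesicle protein, rose by 0.55 ± 0.07, and 1 of its 2 other probes moved the same way. GPR21 and S1PR2, a pair of G protein-coupled receptors with 1 kept probe each, rose by 0.62 ± 0.05 and 0.54 ± 0.04. Among the falls, FBXO48 fell by 0.42 ± 0.04 with Cy5 signal above background on 2 of 8 arrays. PPP1R1B, a phosphatase inhibitor, fell by 0.39 ± 0.06. NFAT5, the transcription factor of osmotic stress, fell by 0.32 ± 0.08, TAF2 by 0.31 ± 0.05, AKR1C3 by 0.31 ± 0.11 and DEDD2 by 0.30 ± 0.03. TAF2 and DEDD2 turned to 0.01 and 0.00 with median centring, which set the median of all genes at 0.205 in FhWey-ES. Over 214 genes called higher that had another kept probe, the other probes showed a median of 0.198 of the tested probe's log2 ratio. Over 190 genes called lower the median was -0.0177, and another probe moved the same way for 20.5% of them.

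By list, the cytosolic ribosomal proteins were the 1 group of 29 that passed camera, limma's test of a list against all other genes, in FhWey-ES. Of 49 measured members, 9 rose, 0 fell and 40 did not pass the test (14 rose and 0 fell when adjusted over the list alone), with a list adjusted p = 0.000307. The call was lost with an adjusted p = 0.404 with an estimated correlation, and at adjusted p = 0.978 with the scanner software's processed signals. RPS18 rose by 0.36 ± 0.13 and RPS27A, which encodes a ubiquitin fused to a ribosomal protein, by 0.30 ± 0.04. In the hypoxia and glycolysis list 6 of 34 members rose and 0 fell, ENO1 among them, but the list missed the threshold at adjusted p = 0.053. In the chemokine list 3 of 11 rose, with CXCL5, a neutrophil attractant, at 0.22 ± 0.05 (list adjusted p = 0.129, or 0.0306 with fry; 5 rose and 2 fell when adjusted over the list alone). PTGES, which makes prostaglandin E, rose by 0.23 ± 0.02, MT3, a metallothionein, by 0.28 ± 0.11, CCNA2, a cyclin of DNA replication, by 0.24 ± 0.06, CIITA, the activator of MHC class II genes, by 0.21 ± 0.09, EGR2, an early response factor, by 0.23 ± 0.08, RAC2, a GTPase of the oxidative burst, by 0.18 ± 0.03, RIGI, a sensor of viral RNA, by 0.27 ± 0.12, and FADS1, a fatty acid desaturase, by 0.23 ± 0.12. STAB1, a scavenger receptor, fell by 0.26 ± 0.08. The falls of MYC (0.17 ± 0.05), the growth regulator, TIMP2 (0.20 ± 0.06), a metalloprotease inhibitor, NPC1 (0.22 ± 0.09), a lysosomal cholesterol exporter, SESN2 (0.25 ± 0.08), a stress response gene, PARP14 (0.20 ± 0.08), an interferon-induced gene, MVD (0.20 ± 0.03), SCD (0.18 ± 0.06) and MDM2 (0.17 ± 0.07) passed the test but turned positive with median centring. In that setting TIMP2, SCD and MDM2 passed as rises in limma (adjusted p = 6.15e-05, 0.00283 and 0.0109). Another probe moved the same way for RPS18, ENO1, MT3, CCNA2 and SCD. None did for PTGES, RAC2, RIGI, FADS1, MYC, TIMP2, SESN2, PARP14 or MDM2. Another probe of NPC1 and the other probe of MVD moved the opposite way.

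The FhWey-ES count changed with each array left out. Limma called 233, 92, 81 and 173 genes without FhWey-ES replicates 1, 2, 3 and 4. It called 1703, 609, 463 and 2602 without FhWild-ES replicates 1, 2, 3 and 4, which share the estimate of the spread. The count thus rose without FhWild-ES replicate 1 or 4 and fell without any other array. Of 39 genes named for FhWey-ES and called in it, 15 passed whichever array was left out, namely ENO1, DNAJB9, RPS27A, GPRC5B, ZNF341, FBXO48, PPP1R1B and the 8 largest rises. The other 24 lost the call without at least 1 array, with the highest adjusted p, 0.212, for MDM2 without FhWey-ES replicate 2. Without FhWey-ES replicate 2 NFKBIA stood at adjusted p = 0.0528, and without FhWey-ES replicate 3 RPS18 stood at 0.0578 and TAF2 at 0.0891.

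FhWild-ES was compared with control cells to ask the same of the other isolate. CTSA, the lysosomal protective protein cathepsin A (UMD_3.1 chromosome 13, 75374544 to 75374603), fell by 0.86 ± 0.16 (SD, n = 4 arrays; adjusted p = 3.88e-06) and was lower on 4 of 4 arrays. AGRN, the basement membrane proteoglycan agrin (chromosome 16, 52673188 to 52673247), fell by 0.80 ± 0.16 (adjusted p = 5.41e-06), and HSPG2, the proteoglycan perlecan, by 0.78 ± 0.17 (adjusted p = 5.41e-06). VEGFA, the vascular growth factor, fell by 0.55 ± 0.16 (adjusted p = 7.4e-05) and MYC by 0.45 ± 0.06 (adjusted p = 2.85e-05). Both other probes of VEGFA fell with it, as did the other probes of CTSA at -0.27 and AGRN at -0.42, while the other probe of MYC read -0.05 and did not pass; for HSPG2, 2 of 5 others moved the same way and 1 the opposite way.

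In FhWild-ES 2731 genes were higher and 2769 lower in limma, with a median absolute log2 ratio of 0.218, a 1.16-fold change. Of these, 1901 of the higher and 2136 of the lower carried a gene symbol. With the arrays of each isolate fitted alone, limma called 3165 genes in FhWild-ES and 3176 in FhWey-ES. The larger count of FhWild-ES, 5500 against 963, was not seen without the shared estimate of the spread. Median centring gave 5473 higher and 1207 lower. A change of at least 1.5-fold was reached by 86 genes, 15 higher and 71 lower. LENG8 (chromosome 18, 63117238 to 63117297) fell by 0.95 ± 0.22, while its 2 other probes had a median of -0.06, and PABPC1L, a poly(A) binding protein with 1 kept probe, fell by 0.98 ± 0.31. AMT, an enzyme of glycine breakdown, fell by 0.93 ± 0.31 with 2 of 3 other probes moving the same way, LY6G5B by 0.79 ± 0.23 with its other probe at -0.19, and CATSPERD by 0.78 ± 0.31 with its other probe at -0.10. The largest rises were those of PTPRC at 0.87 ± 0.10 (other probe 0.21), TYK2 at 0.81 ± 0.12 (other probe -0.24), SS18L1 at 0.81 ± 0.08 (others at a median of -0.05), GPR21 at 0.75 ± 0.11, ATOSB at 0.73 ± 0.13 (other probe -0.06) and SV2A at 0.65 ± 0.18. CAMK1G, a calcium-dependent kinase, rose by 0.64 ± 0.05. RN18S1, an 18S ribosomal RNA, rose by 0.68 ± 0.12, with its other probe at 0.48. Over 964 genes called higher with another kept probe the other probes showed a median of 0.206 of the tested log2 ratio, and over 1460 called lower 0.246.

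**Figure D1:**
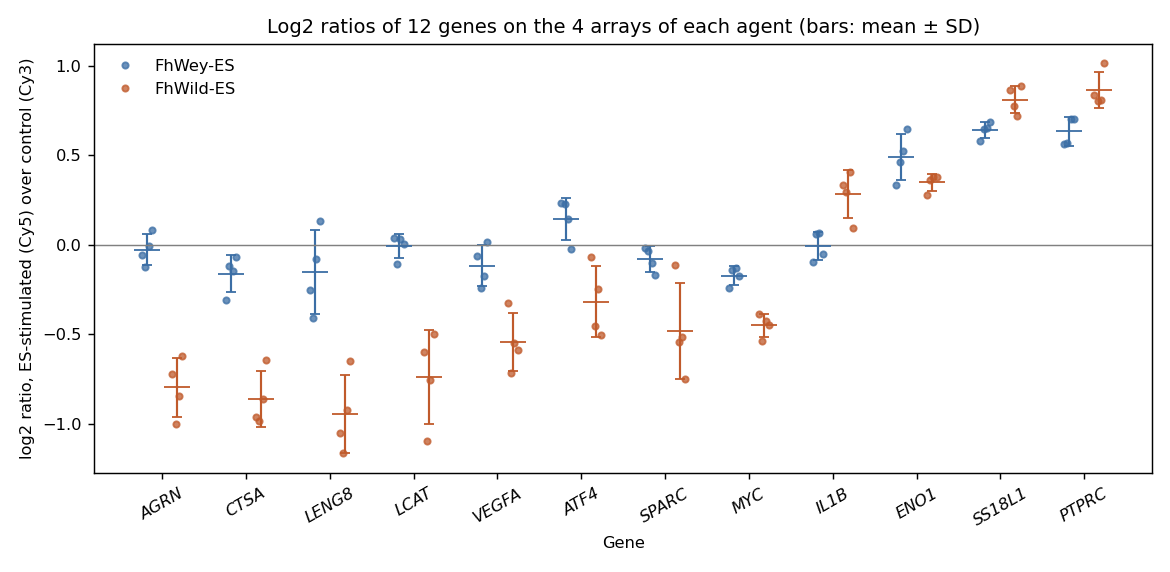
Log2 ratio of ES-exposed over control cells for 12 genes (vertical axis), with 1 point per array, 4 arrays of FhWey-ES and 4 of FhWild-ES, and the mean with its SD. AGRN, CTSA, LENG8 and LCAT lie far below 0 with FhWild-ES and closer to 0 with FhWey-ES, while SS18L1 and PTPRC lie above 0 with both.

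Of 29 lists, 3 passed camera in FhWild-ES, and each moved down. In the lysosome and phagocytosis list 15 of 34 members fell and 1 rose (16 and 1 when adjusted over the list alone; list adjusted p = 0.000915; adjusted p = 0.493 with an estimated correlation). CTSB, a cysteine protease of the lysosome, fell by 0.52 ± 0.20 and LAMP1, an abundant lysosomal membrane protein, by 0.51 ± 0.17, and 1 other probe of each moved the same way. CD68, a macrophage marker of late endosomes, was the member that rose, at 0.15 ± 0.10, though its other probe read -0.07 and did not pass. In the unfolded protein and integrated stress response list 14 of 31 members fell and 1 rose, and the same numbers held when adjusted over the list alone (list adjusted p = 0.00223; adjusted p = 0.145 with an estimated correlation). PDIA6, a disulfide isomerase, fell by 0.47 ± 0.19, SYVN1, a ubiquitin ligase that clears misfolded proteins, by 0.49 ± 0.03, ATF4, the main transcription factor of the integrated stress response, by 0.32 ± 0.20 and SESN2 by 0.40 ± 0.07. No other probe of PDIA6 or SYVN1 passed, and the 2 others of each had a median of -0.05. The chaperone CALR fell by 0.38 ± 0.12, 4 of its 5 other probes fell with it, and its value turned to 0.01 with median centring. DNAJB9, which the unfolded protein response induces, was the member that rose, by 0.41 ± 0.07. In the extracellular matrix and protease list 16 of 33 fell and 2 rose (17 and 4 when adjusted over the list alone; list adjusted p = 0.00867; adjusted p = 0.493 with an estimated correlation). SPARC, a collagen-binding matricellular protein, fell by 0.48 ± 0.27 and all 5 of its other probes fell. COL4A1, a collagen of basement membranes, fell by 0.31 ± 0.11 with 3 of 3 other probes, TIMP2 fell by 0.34 ± 0.06, and COL6A1 fell by 0.42 ± 0.24 with 1 of 2 other probes moving the opposite way. BGN, a small proteoglycan, rose by 0.17 ± 0.11. With median centring the list adjusted p-values were 0.533 for the stress response, 0.0711 for the lysosome and 0.118 for the matrix.

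**Figure D2:**
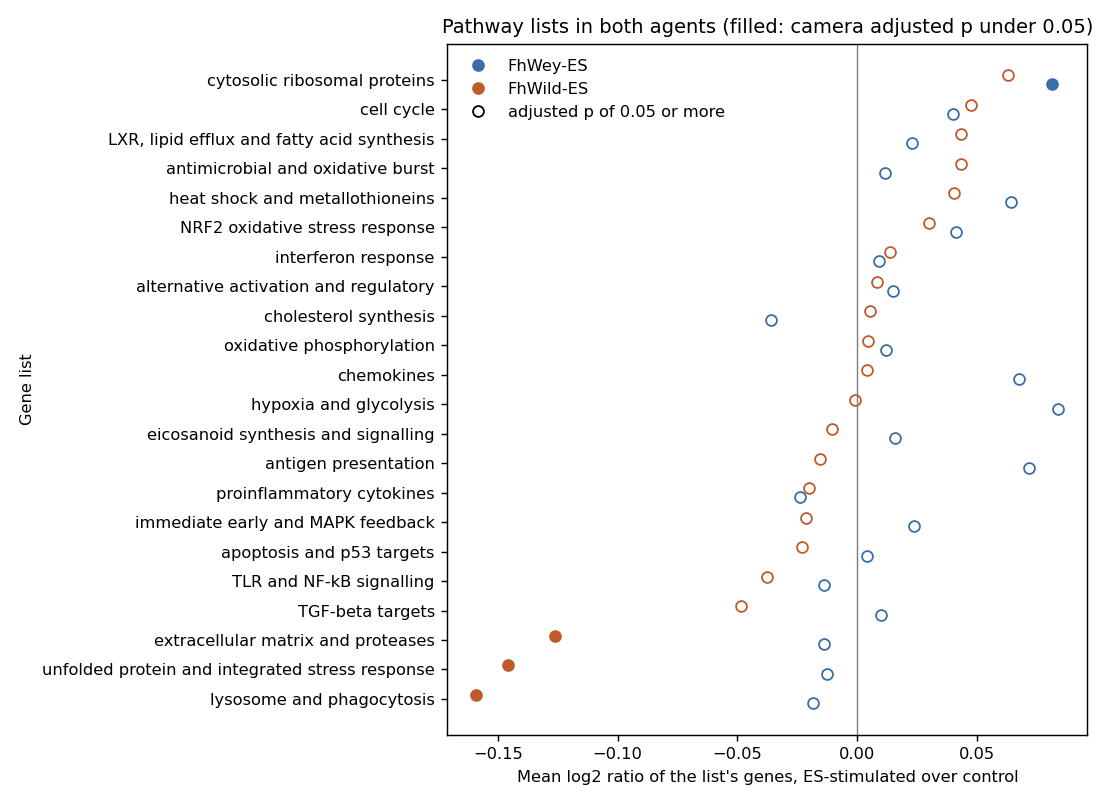
Mean log2 ratio of the measured genes of 22 pathway lists (horizontal axis) in FhWey-ES and FhWild-ES, 4 arrays each; filled points passed camera with the preset correlation. The lysosome, stress response and matrix lists are lowest in FhWild-ES, and the ribosomal protein list is the filled point of FhWey-ES.

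Immune genes moved in both directions in FhWild-ES, and no immune list passed camera. With fry, which tests a list without comparing it to other genes, the TLR and NF-kB list passed as lower (adjusted p = 0.00245). IL1B, the inflammatory cytokine, rose by 0.28 ± 0.13 (adjusted p = 0.00188), while its 2 other probes had a median of 0.09 and did not pass; in FhWey-ES IL1B read -0.01 ± 0.08 (adjusted p = 0.956), where both other probes rose at a median of 0.17. IL10, the anti-inflammatory cytokine, rose by 0.20 ± 0.05 in FhWild-ES (adjusted p = 0.00557) and read 0.06 ± 0.08 in FhWey-ES (adjusted p = 0.491). TGFB1 fell by 0.17 ± 0.11 in FhWild-ES (adjusted p = 0.0208; 0.00 in FhWey-ES), NOS2, the inducible nitric oxide synthase, rose by 0.17 ± 0.15 (adjusted p = 0.0393; 0.05 in FhWey-ES) and ARG1, the arginase of alternative activation, by 0.15 ± 0.08 (adjusted p = 0.026; -0.12 in FhWey-ES). With median centring the FhWey-ES values of IL1B and ARG1 turned to 0.28 and 0.29 and passed (adjusted p = 0.000435 and 0.000335). CXCL8, a neutrophil attractant, passed in neither (0.15 ± 0.11 and 0.12 ± 0.16). Its Cy3 signal was above background on 1 of 8 arrays and its Cy5 signal on 8 of 8, so both ratios are taken against a channel at background. Over the alternatives they ran from -0.0935 to 0.589 in FhWey-ES and from 0.0655 to 0.724 in FhWild-ES, so a change of CXCL8 is neither shown nor excluded. TNF, IL6, CCL2 and PTGS2 were not measurable, since their probes were above background on at most 1 array in either channel. CCL5, a T cell attractant, fell by 0.62 ± 0.22, LTB, lymphotoxin beta, by 0.41 ± 0.05, IKBKB, the kinase that activates NF-kB, by 0.42 ± 0.10, PTGS1 by 0.38 ± 0.10, STAB1 by 0.37 ± 0.09 and CD74, the MHC class II invariant chain, by 0.27 ± 0.24. NFKBIA rose by 0.45 ± 0.20, CCL4 by 0.27 ± 0.04, IFI27, an interferon-induced gene, by 0.39 ± 0.09, LYZ, lysozyme, by 0.32 ± 0.14, PTGES by 0.31 ± 0.08, with 1 of its 2 other probes moving the opposite way, and IRF4 by 0.28 ± 0.07. The 3 other probes of NFKBIA had a median of 0.06, and 1 of them moved the same way. No other probe moved the same way for PTGS1 (2 others, median -0.03) or IFI27 (1 other, -0.02), while 1 of 2 did for CCL5 and 4 of 4 for CD74. The TLR and NF-kB list had 6 members higher and 10 lower of 36 (list adjusted p = 0.331), the interferon list 7 and 7 of 36 (0.861), the chemokines 3 and 2 of 11 (0.738), the proinflammatory cytokines 3 and 2 of 8 (0.951), alternative activation 5 and 3 of 17 (0.804), antigen presentation 3 and 3 of 20 (0.951) and antimicrobial and oxidative burst genes 5 and 2 of 14 (0.331).

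The remaining lists of FhWild-ES did not pass camera, though fry called the ribosomal proteins (adjusted p = 0.00245), lipid efflux and fatty acid synthesis (0.00565) and heat shock (0.00855) as higher. The ribosomal proteins had 17 members higher and 1 lower of 49 (list adjusted p = 0.0794), with RPS27A rising by 0.40 ± 0.09 and RPS3 falling by 0.26 ± 0.20, though RPS3 turned to 0.17 with median centring. Of 4 other probes of RPS3, 0 moved the same way and 1 the opposite way, at a median of 0.04. The cell cycle list had 11 higher and 4 lower of 44 (0.331), with KIF23, a kinesin of cell division, rising by 0.40 ± 0.13 and CCNA2 by 0.38 ± 0.15. In FhWild-ES the 2 other probes of KIF23 had a median of 0.07 and the other probe of CCNA2 read 0.06, and none passed. TGF-beta targets had 2 higher and 8 lower of 25 (0.425), with TAGLN, an actin-binding protein of contractile cells, falling by 0.41 ± 0.24. GADD45B, a stress-induced gene, fell by 0.49 ± 0.11 in a p53 and apoptosis list with 4 higher and 4 lower of 34 (0.747). ENO1 rose by 0.35 ± 0.05 in a hypoxia and glycolysis list with 3 higher and 3 lower of 34 (0.86). ABCG1, a cholesterol exporter, rose by 0.28 ± 0.03, JUNB by 0.28 ± 0.06, MT3 by 0.41 ± 0.12, CCNG1 by 0.37 ± 0.27 and NDUFB3, a subunit of respiratory complex I, by 0.27 ± 0.17. Oxidative phosphorylation had 5 higher and 6 lower of 38 (0.951), cholesterol synthesis 3 and 3 of 23 (0.958), lipid efflux and fatty acid synthesis 4 and 1 of 23 (0.405), NRF2 targets 3 and 1 of 26 (0.747), heat shock 2 and 1 of 20 (0.747), eicosanoids 3 and 2 of 11 (0.951) and immediate early genes 3 and 5 of 27 (0.747). The median, mean and test direction of a list differed in sign in the interferon, hypoxia, cholesterol, fibroblast and epithelial lists of FhWild-ES, in the eicosanoid, TGF-beta, apoptosis and epithelial lists of FhWey-ES, and in the cytokine, interferon, alternative activation, macrophage, NRF2 and cell cycle lists of the difference, none of which passed camera.

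The FhWild-ES count fell to 3249 and 3437 without FhWild-ES replicates 2 and 3, and stood between 4762 and 7005 with each other array left out. Of 72 genes that the naming rule or the examples took for FhWild-ES and that were called in it, 59 passed whichever array was left out. The other 13 lost the call without at least 1 array, with the highest adjusted p, 0.172, for NOS2, whose log2 ratio was 0.10 without FhWild-ES replicate 1. CD74 reached 0.163, TGFB1 0.128 and RPS3 0.0577 without FhWild-ES replicate 2, CD68 reached 0.115 without replicate 1, ARG1 0.103 without replicate 2 and BGN 0.0686 without replicate 4.

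Cells given FhWild-ES were then compared with cells given FhWey-ES, the contrast of the wild with the laboratory isolate. AGRN was lower with FhWild-ES by a log2 difference of -0.77 (95% interval -0.95 to -0.59, n = 4 and 4 arrays; adjusted p = 0.00649) and CTSA by -0.70 (-0.88 to -0.52; adjusted p = 0.00752). LCAT, the enzyme that esterifies cholesterol in lipoproteins (chromosome 18, 35544412 to 35544471), was lower by -0.73 (-0.96 to -0.50; adjusted p = 0.0225), having fallen by 0.74 ± 0.26 in FhWild-ES and read -0.01 ± 0.07 in FhWey-ES. LENG8 was lower by -0.79 (-1.06 to -0.53; adjusted p = 0.0225), PABPC1L by -0.79 (adjusted p = 0.0349), VEGFA by -0.43 (-0.62 to -0.24; adjusted p = 0.033), ATF4 by -0.46 (adjusted p = 0.0349) and MYC by -0.28 (adjusted p = 0.0406). Another probe showed the same difference for AGRN (-0.51), CTSA (-0.31) and LCAT (-0.46) and for both other probes of VEGFA, but not for LENG8 (-0.06) or MYC (-0.06).

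In limma 342 genes differed, 261 lower and 81 higher with FhWild-ES, with a median absolute log2 difference of 0.352, a 1.28-fold difference; 14 reached 1.5-fold, all lower. A gene symbol was carried by 202 of the lower and 49 of the higher. With processed signals 730 were lower and 624 higher. Of the 261, 252 had also fallen in FhWild-ES against control, and their median difference was -0.381 in the Cy5 channel and -0.00212 in the Cy3 control channel. Over 135 of these genes with another kept probe, the other probes showed a median of 0.396 of the tested difference, and 60.7% had another probe that moved the same way. CATSPERD was lower by -0.73, PLPP5, a lipid phosphatase, by -0.67, LY6G5B by -0.60, GADD45B by -0.38, FTH1, the ferritin heavy chain, by -0.33 and LTB by -0.28. Among the higher genes were BDP1, a subunit of an RNA polymerase III initiation factor, at 0.43, NUDT7 at 0.42, NBN, a sensor of DNA breaks, at 0.40, SYNJ1, a phosphoinositide phosphatase, at 0.36, UTS2R at 0.36, CWF19L2, ASCL4 and MROH6 at 0.35 each, IFI27 at 0.31 and CAMK1G at 0.31. BAG3, a co-chaperone, was higher by 0.31, but its 2 other probes were lower and the mean of its probes was -0.07. Over 27 genes called higher with another kept probe, 11.1% had another probe that moved the same way and 14.8% another that moved the opposite way. IL1B differed by 0.29 (adjusted p = 0.0693), ARG1 by 0.27 (0.0529), IL10 by 0.14 (0.262), NOS2 by 0.12 (0.455) and TGFB1 by -0.17 (0.217), and none of these passed.

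The same 3 lists that moved down in FhWild-ES were lower than in FhWey-ES. In the lysosome and phagocytosis list 6 of 34 members were lower and 0 higher (9 and 0 when adjusted over the list alone), with a mean of -0.14 (list adjusted p = 0.000133; adjusted p = 0.63 with an estimated correlation). CTSB was lower by -0.48 (-0.67 to -0.29; adjusted p = 0.0263) and LAMP1 by -0.37 (adjusted p = 0.0444). In the unfolded protein and integrated stress response list ATF4 and SYVN1 (-0.33; adjusted p = 0.0268) were the 2 of 31 that were lower, though the 2 other probes of SYVN1 had a median of 0.01 (6 lower and 1 higher when adjusted over the list alone), with a mean of -0.13 (list adjusted p = 0.000301; adjusted p = 0.0824 with an estimated correlation). In the matrix list COL4A1 (-0.32; adjusted p = 0.0371) was the 1 of 33 that was lower (4 when adjusted over the list alone), with a mean of -0.11 (list adjusted p = 0.0066; adjusted p = 0.63 with an estimated correlation and 0.0551 with median centring). With fry the adjusted p was 0.00216 for the stress response and 0.0658 for both the lysosome and the matrix. Differences that missed the threshold were PDIA6 at -0.36 (0.054), CALR at -0.27 (0.0785), SPARC at -0.40 (0.0741) and COL6A1 at -0.34 (0.161). Of the rest, hypoxia and glycolysis had 1 lower of 34, VEGFA (list adjusted p = 0.143), and antigen presentation had 0 lower and 0 higher of 20 (0.243). All 7 list calls kept their direction in each setting tried.

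The difference count depended on single arrays more than either comparison with control. Limma called 4, 1, 0 and 0 genes without FhWey-ES replicates 1 to 4 (3021, 2530, 2437 and 2493 at an unadjusted p under 0.05) and 1100, 3, 0 and 1973 without FhWild-ES replicates 1 to 4 (4058, 2395, 2505 and 4862). All 32 genes that the naming rule or the examples took for the difference and that were called in it lost the call without at least 1 array, with adjusted p up to 0.068 for AGRN and CTSA without FhWey-ES replicate 3, 0.103 for LENG8 and LCAT without FhWild-ES replicate 3, 0.15 for ATF4 and 0.173 for LTB without FhWild-ES replicate 2. HSPG2 and CAMK1G, named for FhWild-ES, are not among the 32. They lost the call as well. Since 0 genes passed without FhWey-ES replicate 3, no gene could keep the call in every leave-out, so its loss does not rank single genes. With each array left out the log2 difference ran from -0.829 to -0.702 for AGRN, from -0.776 to -0.662 for CTSA and from -0.547 to -0.402 for ATF4. With outlier spots of the scanner software kept, 9 genes differed (2083 at an unadjusted p under 0.05); that a spot marked for its local background also counts as an outlier was settled after the data were examined. Every FhWey-ES array lay on 1 slide and every FhWild-ES array on the other, so isolate, slide, labelling batch and exposure time cannot be told apart.

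Many genes were called in the comparisons of both isolates with control. Of 568 genes higher in FhWey-ES, 409 (72%) were also higher in FhWild-ES, against 87.9 for independent lists of these sizes, and of 395 lower ones 248 (62.8%) were also lower, against 62. Opposite calls were made for 2 and 3 genes. The numbers for independent lists leave out what the comparisons share, which is the dye orientation, the estimate of the spread and, if the same wells were used, control RNA. ENO1, NFKBIA, DNAJB9, MT3, CCL4, CXCL5 and RPS27A rose in both, and GPRC5B, STAB1, TIMP2 and SESN2 fell in both. With median centring TIMP2 passed as a rise in FhWey-ES (0.333; limma adjusted p = 6.15e-05), and SESN2 turned to 0.111 there without passing. The other probe of SESN2 passed in neither isolate (-0.09 in FhWey-ES and -0.03 in FhWild-ES). Across the 17647 genes, which are not independent replicates, the 2 sets of log2 ratios had a Pearson r of 0.608 and a Spearman rho of 0.582. Simulated arrays with no effect and wholly shared control RNA gave an r of 0.499 and a covariance of 0.0016, against 0.01 observed. With 2 replicate numbers of 1 isolate set against the other 2 of the other isolate, r was 0.33 to 0.54. Cy5 held the exposed cells on every array, so a constant dye effect of a probe would also enter both ratios. Among genes higher in both, the other probes showed a median of 0.126 of the tested log2 ratio of FhWild-ES over 154 genes (95% interval 0.0709 to 0.182), and among genes lower in both 0.171 over 132 genes (0.0839 to 0.221).

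The hypoxia and glycolysis genes varied between arrays of 1 isolate. The mean log2 ratio of the list was 0.01, 0.02, 0.03 and 0.26 on FhWey-ES arrays 1 to 4 and -0.04, -0.08, -0.02 and 0.13 on FhWild-ES arrays 1 to 4. On array 4 ADM, a vasodilator peptide induced by low oxygen, lay above its isolate's mean by 0.44 in FhWey-ES and 0.61 in FhWild-ES, NDRG1 by 0.46 and 0.34, and ANKRD37 by 0.55 and 0.53. Other members lay below it there, HIF1A at -0.09 and -0.27, BNIP3L at -0.05 and -0.29 and GPI at -0.02 and -0.29. In the Cy3 channel, the control cells, the list lay below its isolate's mean on array 4 of both slides, at -0.143 and -0.138. With arrays 2 and 3 of each isolate alone, chosen after the data were examined, limma called 3007 genes in FhWey-ES, 7754 in FhWild-ES and 2331 in the difference.

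**Figure D3:**
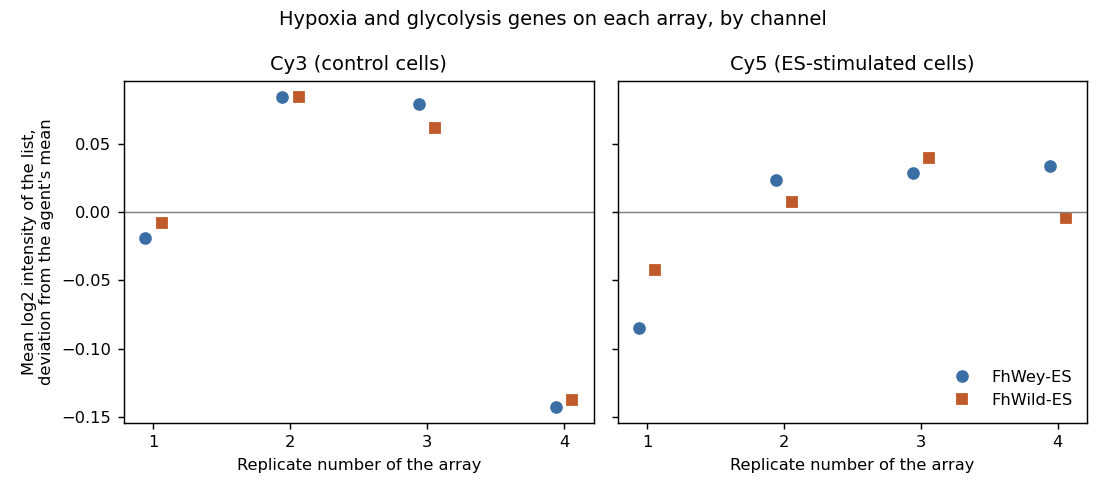
Deviation of the mean log2 intensity of the hypoxia and glycolysis list from its mean over the 4 arrays of the same isolate (vertical axis) by replicate number, in the Cy3 control channel and the Cy5 channel. The Cy3 values of FhWey-ES and FhWild-ES lie close together at each number, lowest on array 4.

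The control cells of the 2 sets of arrays were compared in the Cy3 channel alone. INS, the insulin gene, was higher on the FhWild-ES arrays by 0.32 and TSPAN11, a tetraspanin, by 0.56 (adjusted p = 0.0285 for both), and these 2 of 17647 genes passed in limma, with 1109 at an unadjusted p under 0.05. Both were named after their values were seen. Same-numbered arrays deviated together in Cy3, and with the replicate number as a block 0 genes passed in limma (2256 at an unadjusted p under 0.05). Limma called 0 genes without FhWey-ES replicate 2, 3 or 4 (811, 830 and 952 at an unadjusted p under 0.05) or FhWild-ES replicate 1 or 3 (878 and 818), 1 without FhWey-ES replicate 1 and 6 without FhWild-ES replicate 4.

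Markers of macrophages and of other cell types were examined as a description of the line. Of 27 macrophage identity genes on the array, 13 (48.1%) were above background, against 12 of 13 epithelial, 11 of 16 fibroblast, 12 of 22 T and NK cell, 6 of 9 B cell, 5 of 16 neutrophil and 5 of 14 endothelial and mural markers. Of all 17373 gene symbols on the array, 12700 were tested, a larger share than that of the macrophage genes. In FhWild-ES the macrophage list had 5 members higher and 1 lower of 13 (list adjusted p = 0.255), with PTPRC higher and SPI1, the master transcription factor of macrophages, falling by 0.75 ± 0.28 (adjusted p = 0.00031). The T and NK markers had 6 higher and 1 lower of 12 (0.0794), CD247 falling by 0.40 ± 0.19 and CD3D rising by 0.25 ± 0.10. The B cell markers had 2 higher and 0 lower of 6 (0.0814), the fibroblast markers 2 and 3 of 11 (0.958), the neutrophil markers 2 and 0 of 5 (0.331), the endothelial markers 1 and 0 of 5 (0.636) and the epithelial markers 3 and 4 of 12 (0.747), MUC1 falling by 0.49 ± 0.15. CD3D differed between the isolates by 0.32 (adjusted p = 0.037), and SPI1 by -0.57 without passing (adjusted p = 0.0706). None of these 7 marker lists passed camera in any comparison. Fry called the T and NK, B cell and neutrophil lists (adjusted p = 0.00245 each), the macrophage list (0.00565) and the endothelial list (0.0487) as higher in FhWild-ES, and the macrophage (0.0424) and endothelial (0.0152) lists in FhWey-ES.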

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

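The tests of control RNA, of probe GC content and of slides were chosen only after the result was seen, while the splits of the arrays were set before the counts they test were seen. FhWild-ES and FhWey-ES differed for 342 genes in the test of the difference, and the means of 3 lists differed: -0.13 for the unfolded protein and integrated stress response, -0.14 for the lysosome and -0.11 for the matrix. These list calls were lost with an estimated correlation, at adjusted p = 0.0824, 0.63 and 0.63 with an estimated correlation. Lower with FhWild-ES were AGRN (-0.77), ATF4 (-0.46), CATSPERD (-0.73), COL4A1 (-0.32), CTSA (-0.70), CTSB (-0.48), FTH1 (-0.33), GADD45B (-0.38), HSPG2 (-0.55), LAMP1 (-0.37), LCAT (-0.73), LENG8 (-0.79), LTB (-0.28), LY6G5B (-0.60), MYC (-0.28), PABPC1L (-0.79), PLPP5 (-0.67), SRSF4 (-0.28), SRSF5 (-0.43), SYVN1 (-0.33) and VEGFA (-0.43). Higher were ASCL4 (0.35), BAG3 (0.31), BDP1 (0.43), CAMK1G (0.31), CD3D (0.32), CWF19L2 (0.35), IFI27 (0.31), MROH6 (0.35), NBN (0.40), NUDT7 (0.42), SYNJ1 (0.36) and UTS2R (0.36). Another probe moved the same way for AGRN, CTSA, LCAT, VEGFA, COL4A1, CTSB and SRSF5 among others, and the other probes of BAG3 moved the opposite way. No other probe moved the same way for LENG8, CATSPERD, LAMP1, MYC, SYVN1, BDP1, NUDT7, SYNJ1, UTS2R, CWF19L2 or IFI27. For HSPG2, 2 of 5 others moved the same way and 1 the opposite way.

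The genes lower with FhWild-ES than with FhWey-ES numbered 261, among them AGRN, CTSA, LAMP1 and ATF4. Control RNA that differed between the sets of arrays is argued against, since a rise of Cy3 accounted for a median share of -0.0056 of the fall (95% interval -0.026 to 0.0046). A trend with probe GC content is argued against as the whole cause, since 255 of the 261 (97.7%) stayed lower and past the threshold after it was removed. Slide, labelling batch and length of exposure cannot be told apart from the isolate, because 0 slides held arrays of both. A difference between the isolates' products remains among the open explanations.

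Splits of the arrays asked how often other groupings gave as many genes. For FhWey-ES against control 1 of 8 sign splits gave as many, with 963 genes in the real one and at most 0 in the others in limma (58 to 825 at an unadjusted p under 0.05), and for FhWild-ES 1 of 8, with 5500 and at most 0 (48 to 4369). These 8 splits are too few for a share under 0.05. For the difference of the isolates 2 of 35 splits gave as many as 342, and the highest other, FhWey-ES replicate 1 with FhWild-ES replicates 1, 2 and 3 against the rest, gave 771, so chance was not excluded and the larger count points to a structure of the samples.

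Single arrays stood apart for 18 of 240 groups of 4 arrays tested, against 12 that chance would give. In FhWey-ES these were AKR1C3 on array 4 (-0.47), CWF19L2 (0.21), CYC1 (0.04), MAT2A (0.23), PDIA6 (-0.21), RPS27A (0.37), SYVN1 (-0.28) and UTS2R (-0.081) on array 1. In FhWild-ES they were EGR2 (0.42) on array 1, ABCG1 (0.23), CCL5 (-0.94), FBXO48 (-0.30) and TIMP2 (-0.43) on array 2, PPP1R1B (-0.38) on array 3, and MT3 (0.59), PDIA6 (-0.19), PTPRC (1.0) and RPS18 (0.50) on array 4. In the control spots, which no comparison used, 10 spike-in probes with 32 spots each were above background on every array, with mean log2 ratios from -2.15 to 3.35 in FhWey-ES and from -2.37 to 3.14 in FhWild-ES before normalization. All 10 were lower on the FhWild-ES arrays, by -0.16 to -0.28. Spike-in RNA is added and is not made by the cells, so that shift is not a change of their genes. The median ratio of gene spots before normalization was lower there by -0.59, a shift that goes with slide and isolate alike.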

How the results depend on the processing

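Agreement of another probe, arrays 2 and 3 alone, the hypoxia covariate and the GC correction were tests chosen only after the result was seen; the other alternatives were fixed beforehand. Of 3958 pairs of a named gene and a setting (157 values, 27 settings), 3284 kept direction and side of the threshold, 592 kept direction and lost the call, 43 gained one, 17 turned and were called before or after turning (5 after it), and 22 turned without a call before or after. Main counts of genes were 963 for FhWey-ES, 5500 for FhWild-ES and 342 for the difference of the isolates, and where they changed by more than 1.5-fold the cause was not tested, apart from the stricter requirement in the fold and probe settings. Without background subtraction FhWey-ES had 1995. With processed signals FhWey-ES had 3307 and the difference 1354, with series matrix values 3306 and 1354, and with median centring 12890 and 3858. Median centring moved the median of all genes to 0.205 in FhWey-ES, 0.0728 in FhWild-ES and -0.0865 in the difference. Scale normalization gave 2288 and 187, no filter gave FhWey-ES 1722 and an intensity trend gave the difference 213. Outlier spots kept gave 385, 3245 and 9 (2083 at an unadjusted p under 0.05). Array weights gave 5238, 8756 and 3797, and a 1.5-fold minimum gave 6, 86 and 14. Fits of 1 isolate alone gave 3176 and 3165, and Cy5 alone gave a difference of 580. Agreement of another probe gave 128, 1061 and 88; arrays 2 and 3 alone gave 3007 in FhWey-ES and 2331 in the difference; the hypoxia covariate gave 1942 and 1066. Leave-outs ranged from 81 to 2602 in FhWey-ES, 3249 to 7005 in FhWild-ES and 0 to 1973 in the difference (2395 to 4862 at an unadjusted p under 0.05 in limma).

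The Cy3 count of 2 became 1 with 75th percentile scaling, 0 with no filter (2145 at an unadjusted p under 0.05), 0 with the replicate block (2256), and 0 to 6 in leave-outs. List counts of 1, 3 and 3 became 0, 0 and 0 with an estimated correlation (1 list each at an unadjusted p under 0.05), 5, 12 and 1 with fry, and 12, 6 and 7 with median centring. Processed signals gave 0 lists in FhWey-ES (5 at an unadjusted p under 0.05). Leave-outs gave 1 to 3 lists in FhWey-ES and 3 to 5 in the difference. The correlation of the isolates, 0.608, ran from 0.55 to 0.627 in leave-outs, 0.636 with processed signals and 0.576 with median centring.

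With the replicate block the difference had 2518 genes. The block was read as an alternative only, since same-numbered arrays correlated in their ratios at 0.61, 0.32, 0.07 and 0.58, and pair 3 fell under 0.1. In their ratios 6 of 8 arrays correlated best with their own number. In Cy3 the 4 pairs stood at 0.39, 0.30, 0.19 and 0.53 and 7 of 8 arrays did so, a hint of pairing from the data. In Cy5 the pairs stood at 0.57, 0.082, -0.041 and 0.59, and 4 of 8 arrays did so. The match of pairs 1 and 4 was therefore not confined to the control channel. A slide block could not be fitted, because each slide holds 1 isolate, and was not run.

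With median centring these changed sign in FhWey-ES: TAF2 0.00743, DEDD2 0.00423, PARP14 0.0202, SESN2 0.111, MVD 0.101, SCD 0.218, MDM2 0.173, NPC1 0.122, TIMP2 0.333, MYC 0.117, IL1B 0.277 and ARG1 0.289. In FhWild-ES CYC1 0.103, RPS3 0.174 and CALR 0.0103 did so. With the mean of probes NPC1 was 0.0164 in FhWey-ES and BAG3 -0.0684 in the difference. The cause was not tested. Signal over background limits the cytokine lists, of which 8 of 20 proinflammatory cytokines and 11 of 24 chemokines on the array were kept.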

Other observations

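The tests of other probes and of the hypoxia list were chosen only after the result was seen, and the list of genes known for transcripts with detained introns was drawn up before its members' values were seen, prompted by other genes of this kind (LENG8, LUC7L, NXF1 and CCNL2), which were left out of it. Detained introns keep transcripts, many of splicing factors, in the nucleus, and the probe signal of most genes of the list fell with FhWild-ES. Of 30 measured genes of this list, 20 fell and 1 rose against control, with a median log2 ratio of -0.19 over the list. OGT, the enzyme that adds O-linked N-acetylglucosamine, fell by 0.47 ± 0.06 (SD, n = 4 arrays; adjusted p = 5.42e-05), SRSF5, a splicing factor, by 0.49 ± 0.18 (adjusted p = 0.000252) and MAT2A, which makes S-adenosylmethionine, by 0.46 ± 0.33 (adjusted p = 0.00349). Against FhWey-ES, 4 of the 30 were lower and 0 higher, among them SRSF5 (-0.43; adjusted p = 0.0419), SRSF4 (-0.28; 0.0421) and DDX5 (-0.25; 0.05), with a list p of 4.69e-07 and p = 0.00365 with an estimated correlation. Both other probes of SRSF5 and the other probe of MAT2A moved the same way. A candidate explanation is a change in nuclear retention or splicing with FhWild-ES, but introns were not measured and the probes were not mapped to exons or introns. It was found and tested on the same arrays, and slide and exposure time differ with the isolate.

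Rises shared by both isolates numbered 409, with PTPRC, SS18L1, TYK2 and ATOSB at the top. A probe-specific dye effect may account for part of them, since the other probes of the same genes showed a median of 0.126 of the log2 ratio (95% interval 0.0709 to 0.182; 154 genes). The tested probe was the brightest of its gene and the genes were selected by its call, either of which could lower this share as well. Genes lower with FhWild-ES than with FhWey-ES, where a constant dye effect cancels, had a share of 0.396 (0.347 to 0.454; 135 genes), but genes higher with FhWild-ES, where it cancels too, had 0.0256 (-0.135 to 0.172; 27 genes), so a low share is not specific to a dye effect. A response of the cells to both products remains open, as for ENO1, where 2 of 4 other probes rose in FhWey-ES, and for 63 of the 154 genes (40.9%) with another probe that moved the same way in FhWild-ES. For 18 of the 154 genes (11.7%) another probe moved the opposite way.

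The hypoxia and glycolysis list varied between arrays of 1 isolate with an SD of 0.106, at percentile 100 of 10000 random lists matched on intensity (the median SD of these was 0.0205), which shows only that it varied and does not test oxygen or cell density in the wells as the cause. The 95% interval of random lists ended at an SD of 0.0464. Position on the slide acting alike on both channels cancels in the ratio by definition, so the SD of the ratio cannot test it. An equal effect on both channels is argued against for array 4, which deviated by -0.143 and -0.138 in Cy3 but by 0.0339 and -0.00414 in Cy5. Control RNA of the same number on both slides is a further candidate explanation, since pairing arrays by number gave the closest match of the Cy3 values in 1 of 24 pairings (exact p = 0.0417, one-sided, the smallest that 24 pairings can give). Position follows the replicate number on both slides, so an effect of position on Cy3 alone would give the same match. In the check of same-numbered arrays above, Cy5 correlated at 0.57 and 0.59 for numbers 1 and 4, but at 0.082 and -0.041 for numbers 2 and 3. Cy5 holds the exposed cells, so shared control RNA would not by itself give the Cy5 match of numbers 1 and 4. With shared control RNA the 8 control values would come from fewer control wells than arrays, and the labels do not settle it.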
